A study of Mus musculus with 9 samples.

How the data were processed

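Corneal grafts of mice were taken on day 15 and dissociated, and single cells were captured in droplets and sequenced from the 3' end, per the labels' protocols, which describe enzymatic dissociation with trypsin. There were 9 libraries, 1 in each of 9 groups. Per the submitters' processing notes, reads were handled with CASAVA, aligned with STAR to the mm10 build, counted with featureCounts and analysed with Seurat, with no versions given. The deposited files held counts, whole UMI numbers per gene and barcode, with no cell annotation, and the genes were 32285 with symbols and Ensembl identifiers. Gene positions came from the GENCODE M21 annotation of GRCm38, the assembly of mm10. Libraries were grouped by their titles, and for 2 antibody libraries the title and the deposited name conflict. The median depth of a library was 3138 to 11914 UMIs per barcode.

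Barcodes were kept with at least 300 genes and at most 20% mitochondrial UMIs. Doublet scores from simulated doublets (the scrublet method), computed within each library, set automatic thresholds that marked only 0 to 1.77% of cells, so the 6% of cells with the highest doublet scores in each library were removed instead. That choice was made after the thresholds were seen. It left 95701 cells of 103145 barcodes, 6612 to 12839 per library. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes chosen within libraries and 30 principal components were taken with no integration of libraries, and cells were clustered with the Leiden method at resolution 1 on a graph of 20 nearest neighbours weighted by shared neighbours. Immune clusters, vascular clusters and another set of small or mixed clusters were each clustered once more, with 20 components. Clusters were named by hand after their profiles were seen, from marker genes fixed beforehand, with at least 3 markers found in 10% of the cluster's cells, no more markers of another class than of its own among its top 10 genes, and no name for clusters with a median UMI count under 1/3 of their own libraries' and no own markers among those genes. The 4 unnamed clusters given as of low UMI content had medians of 0.206 to 0.414 of their own libraries', and were left out by hand after the data had been seen because they mixed markers of several classes, not by that limit alone. This gave 16 named classes from 58 of 79 clusters. The keratocyte cluster alone was added as a class after the data had been seen.

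UMIs were summed per library and class, scaled to CPM (counts scaled to the same total), and compared as the log2 ratio of CPM + 10. With 1 library per group there was no test. Shares have exact Clopper-Pearson 95% intervals, ratios of sums exact conditional binomial intervals, and list medians intervals from 2000 Poisson redraws of the counts. Against a count of 0 a fold is a lower bound with 3 counts set over the class sum of that library. Classes entered gene comparisons with at least 100 cells in both libraries, except the monocyte/macrophage comparison of PBS with the isograft. A list median took members with at least 20 UMIs in 1 of the libraries, and was set against 10000 random lists of the same size matched on mean expression. A list was called higher or lower at 1.5-fold and outside percentiles 2.5 to 97.5. The 9 comparisons, the marker genes, 31 gene lists, the rule for named genes and the alternatives, apart from 3, were fixed before the data were examined. The 2 comparisons between antibody libraries were added later.

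Named genes were the 3 highest and 3 lowest by log2 ratio in each class, with at least 50 UMIs in the higher library, at least 2-fold apart with the interval wholly beyond 1.5-fold, and with CPM at least 20% of the highest class of that library. Mitochondrial, ribosomal, predicted, haemoglobin, immunoglobulin, T cell receptor segment, sex-linked and H2 genes were left out. List members furthest from 0 could be named besides. RNA of immune cells in epithelial-like cells and in the keratocyte cluster was gauged, after the data had been seen, as the CPM there of the T, NK, B, monocyte/macrophage and dendritic markers with at least 50 UMIs in immune cells, over their CPM in all immune cells. The rule covered T cell-like, neutrophil-like, monocyte/macrophage-like, dendritic-like, stromal, corneal endothelial-like and vascular endothelial-like cells, and later the keratocyte cluster. Genes among the 10 leading genes of a cluster of the same class, against all other cells or within the second clustering, were not named, and values of 1 cluster or T cell subset were held to the leading genes of that cluster or subset alone. Alternatives were a limit of 10% mitochondrial UMIs, at least 500 genes, doublets kept, each cell classed alone by its marker score, resolution 2, other denominators, a pseudocount of 1 CPM, no filter on list members, a median-of-ratios scaling, and cells thinned to 1000 UMIs. The 3 added later were shares without the 4 clusters of low UMI content, shares among named classes only, and the C1q cluster in place of all monocyte/macrophage-like cells.

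The gene and list steps were tested on simulated counts made from the tacrolimus and PBS monocyte/macrophage-like sums. Among 5667 genes, 39 of 100 genes set 2-fold apart and 100 of 100 set 4-fold apart met the rule in the right direction, and 2 unchanged genes met it. Of 200 unchanged lists of 18 genes, 4.50% lay outside the central 95% of random lists. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.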

Results

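RNA of single cells was counted as UMIs (unique molecular identifiers, 1 per captured RNA molecule) in 9 libraries of mouse corneal grafts taken on day 15, with 1 library per group. There were no replicates, so no test across animals was made, and each difference is one between 2 libraries. The allografts were C57BL/6 corneas on BALB/c recipients and the isograft was BALB/c on BALB/c. A first set of 4 libraries held allografts given PBS, rapamycin or tacrolimus, and an untreated isograft. A second set of 5 held allografts given IL-19, demeclocycline (a tetracycline antibiotic), or tacrolimus with an antibody to Gr-1 (the Ly6G and Ly6C surface proteins of neutrophils and monocytes) on day 0 to 7, day 8 to 15 or day 0 to 15. Doses were not given. The protocol names 4 corneas, and the labels did not say whether a library was 1 cornea or a pool. For 2 of the antibody libraries the title and the deposited name gave each other's day ranges, so these are called by their titles as the library labelled day 8 to 15 and the library labelled day 0 to 15.

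Total counts ran from 79954592 UMIs in the IL-19 library to 133742186 in the library labelled day 0 to 7, over 7197 to 13715 barcodes. The median UMIs per deposited barcode, before cells were filtered, were 3568 with PBS, 4241 with rapamycin, 5888 with tacrolimus, 7904 in the isograft, 4388 with IL-19 and 3138 with demeclocycline. They were 7983, 11914 and 9078 in the libraries labelled day 0 to 7, day 8 to 15 and day 0 to 15. Epithelial-like cells (Krt5, Krt12 and Krt14 clusters) were the largest class in each library, from 39.5% with IL-19 to 83.1% in the library labelled day 0 to 15. All immune classes together made up 20.2% of kept cells with PBS, 4.67% with rapamycin, 6.54% with tacrolimus, 2.02% in the isograft, 22.9% with IL-19 and 6.32% with demeclocycline. In the libraries labelled day 0 to 7, day 8 to 15 and day 0 to 15 they made up 26.9%, 18.2% and 3.48%. The 4 clusters of low UMI content, left unnamed by hand after the data had been seen, held 21.8% of cells with PBS, 9.61% with rapamycin, 17% with tacrolimus, 0.139% in the isograft, 13.2% with IL-19 and 32.4% with demeclocycline, and at most 0.0302% in the antibody libraries. Ranges in parentheses are exact 95% intervals that cover counting error only, and ratios of shares are log2. Gene values are CPM, the counts of a class scaled to the same total, with log2 ratios taken after adding 10 CPM to each. List medians lay outside the central 95% of those of 10000 random lists matched on expression unless stated.

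**Figure D1:**
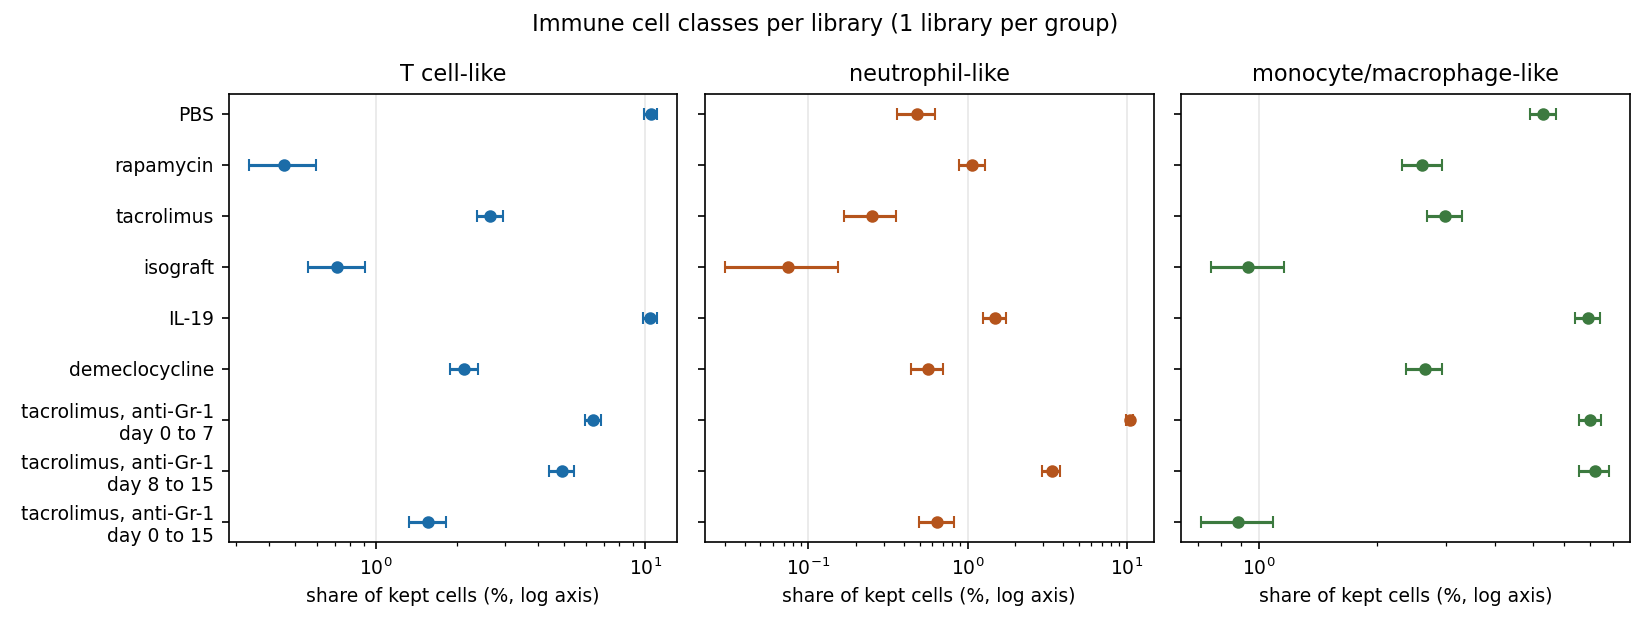
Share of kept cells (percent, log axis) in the T cell-like, neutrophil-like and monocyte/macrophage-like classes of each library, with exact 95% binomial intervals as bars. T cell-like cells were 10.5% with PBS and 0.454% with rapamycin, and neutrophil-like cells were 10.4% in the library labelled day 0 to 7.

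The PBS allograft against the isograft asked how the graft differs when donor and recipient are not matched. The donors of these grafts were also of different strains. Donor strain and mismatch therefore cannot be told apart in any share or gene value that includes donor cells. T cell-like cells made up 10.5% (9.93 to 11.1%) of the PBS allograft and 0.717% (0.556 to 0.909%) of the isograft, a log2 ratio of 3.87 (3.52 to 4.25). NK-like cells (4.22, 3.27 to 5.37), dendritic-like cells (2.92, 2.17 to 3.76) and monocyte/macrophage-like cells (2.50, 2.17 to 2.84) also had higher shares. B cell-like cells were 0.332% (0.235 to 0.456%) of the PBS allograft and 0 of 9350 cells in the isograft, which allows a share of up to 0.0394%. Epithelial-like cells had a lower share, -0.92 (-0.98 to -0.87). Among immune cells alone the T cell log2 ratio was 0.55, and those of monocyte/macrophage-like and dendritic-like cells turned to -0.82 and -0.40.

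Interferon-gamma response genes were higher in the PBS allograft in each class compared. In monocyte/macrophage-like cells their median log2 ratio was 2.06 with 18 of 18 at least 1.5-fold higher, percentile 100 among random lists, or 2.01 with the genes at 0 set to their lower bound. Gbp2, an interferon-induced GTPase, stood at 177 against 11.8 CPM, log2 ratio 3.10. Only 88 isograft cells entered, of which 85.2% lay in the C1q cluster, while 67.1% of the 608 PBS cells lay in the Ly6c2 cluster. Dissociation stress genes were lower there, median -0.83, and genes of glycolysis higher, median 0.94.

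The same list was higher in epithelial-like cells (median 2.07 with 17 of 18 at least 1.5-fold higher), in the keratocyte cluster of the stroma (2.78 with 15 of 17 at least 1.5-fold higher) and in vascular endothelial-like cells (2.27 with 17 of 17 at least 1.5-fold higher). Cd74, the invariant chain of MHC class II (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652), was 1177 against 7.00 CPM, log2 ratio 6.13 in epithelial-like cells, and type I interferon genes had a median of 2.27. In the keratocyte cluster Cxcl9, a chemokine that draws activated T cells (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079, GRCm38), was 2039 against 0.866 CPM, 2355-fold higher with an interval of 805 to 11423, and Cxcl10, a chemokine of the same receptor, 901 against 41.6 CPM, log2 ratio 4.14. Vascular endothelial-like cells held Tgtp2, an interferon-induced GTPase, at 665 against 27.9 CPM, log2 ratio 4.16, and the vascular cluster led by Selp, Csf3 and Egr4 held 11.8% of these cells with PBS and 29.5% in the isograft. The median ratio of genes with at least 50 UMIs in both libraries stood at 0.15 log2 in epithelial-like cells, and the epithelial medians lie above that shift. MHC class I and II genes of the H2 locus can differ between the strains against the reference, so Cd74 is given for class II. Whether the other genes and lists, those of interferon included, differ by donor strain was not tested. In epithelial-like cells with PBS Cd74 stood at 10.3% of its CPM in all immune cells together. There 43 immune marker genes had a median of 0.428% and at most 1.67% by cell type, a level that free RNA can give. In the keratocyte cluster Cd74 stood at 0.839%, against a marker median of 0.775% and at most 0.964% by cell type, so it lay at that background. In isograft epithelial-like cells it stood at 0.0389% against a marker median of 0.0261%, close to that background. RNA quality genes in vascular endothelial-like cells had a median of -0.64. Genes of T cell-like cells were not compared, since the isograft had 67 such cells.

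Tacrolimus blocks calcineurin, which activates NFAT in T cells, and its comparison with PBS asked which cells and genes differ under it. T cell-like cells made up 2.66% (2.38 to 2.96%) with tacrolimus and 10.5% with PBS, a log2 ratio of -1.98 (-2.16 to -1.80). NK-like (-4.29, -5.32 to -3.42), dendritic-like (-1.64, -2.13 to -1.16) and monocyte/macrophage-like cells (-0.83, -1.03 to -0.64) had lower shares as well, and epithelial-like cells a higher one (0.55, 0.50 to 0.60). Without epithelium the T cell log2 ratio was -1.40, among immune cells alone -0.36, and that of monocyte/macrophage-like cells among immune cells turned to 0.79. Dendritic-like cells were 50 of 786 immune cells with tacrolimus and 148 of 2306 with PBS, similar parts. Of the T cell-like cells, CD4 made up 29.2% with tacrolimus and 40.6% with PBS, CD8 42.3% and 35%, gamma-delta 21.3% and 11.4%, and regulatory 7.21% and 12.9%.

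T cell-like cells with tacrolimus held more Nr4a2, a nuclear receptor switched on by T cell receptor signals (ENSMUSG00000026826, chromosome 2, 57106830 to 57124003), at 334 against 68.9 CPM, log2 ratio 2.12. Hk2, the hexokinase of glycolysis, was 128 against 27 CPM, log2 ratio 1.90, and Ifng, the interferon-gamma gene (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892), was 576 against 182 CPM, log2 ratio 1.61 in CD8 cells. Genes that calcineurin and NFAT drive were higher by less than 1.5-fold, median 0.37 with 6 of 16 at least 1.5-fold higher. Without 6 immediate-early genes that dissociation can switch on, Nr4a2 among them, the median was 0.0776 (-0.17 to 0.31) at percentile 83.3, within the random range. Type 17 genes had a median of 0.63 with 6 of 9 at least 1.5-fold higher, beside the higher gamma-delta share. Regulatory T cell genes were lower (median -0.88 with 11 of 14 at least 1.5-fold lower), beside the lower regulatory share. Proliferation genes were lower (median -0.60 with 12 of 21 at least 1.5-fold lower), with Ube2c, a mitotic ubiquitin ligase partner, at 27.4 against 153 CPM, log2 ratio -2.12. Gzmf, a granzyme of long-activated killer cells, was 1.14 against 143 CPM, 126-fold lower with an interval of 22.5 to 4977. Haemoglobin genes, which red cells make, were lower in these T cell-like cells, median -4.84.

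In monocyte/macrophage-like cells the interferon-gamma response list was lower by less than 1.5-fold, median -0.32 with 5 of 18 at least 1.5-fold lower, percentile 0.130, and -0.76 with each cell thinned to 1000 UMIs. That thinning left out 13 of 358 tacrolimus and 58 of 608 PBS cells. Cxcl9 in the C1q cluster alone was 291 against 947 CPM, log2 ratio -1.67. In the whole class Ly6a, an interferon-induced surface antigen, was 202 against 1019.8 CPM, log2 ratio -2.28, and Nos2, the inducible nitric oxide synthase, 2.93 against 35.6 CPM, log2 ratio -1.82. Cd207, the langerin gene, was 52.7 against 1.75 CPM, log2 ratio 2.41. Glycolysis genes had a median of -0.61. The C1q cluster held 68.4% of these cells with tacrolimus and 21.2% with PBS.

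Donor and recipient cells were not told apart in the allografts, so class I and II medians hold H2 genes of both strains in unknown parts. Epithelial-like cells with tacrolimus had lower class II genes (median -1.74) and class I genes (median -0.67). In the keratocyte cluster Cxcl9 was 592 against 2039 CPM, log2 ratio -1.77 and Penk, the proenkephalin gene, 986 against 232 CPM, log2 ratio 2.04. Vascular endothelial-like cells had higher type I interferon genes, median 0.86 with 11 of 13 at least 1.5-fold higher, among them Rsad2, the antiviral viperin gene, at 145 against 26.4 CPM, log2 ratio 2.08, while Lcn2, an iron-binding acute-phase protein, was 124 against 485 CPM, log2 ratio -1.88. RNA quality genes were higher in those cells, median 0.93, and the vascular cluster led by Selp, Csf3 and Egr4 held 36.1% of them with tacrolimus and 11.8% with PBS.

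Rapamycin blocks the growth kinase mTORC1. T cell-like cells made up 0.454% (0.337 to 0.597%) with rapamycin, a log2 ratio to PBS of -4.53 (-4.97 to -4.12), and NK-like (-3.82, -4.72 to -3.04), dendritic-like (-1.95, -2.51 to -1.42) and monocyte/macrophage-like cells (-1.02, -1.23 to -0.82) had lower shares. Mural-like (2.78, 2.22 to 3.38), melanocyte-like (2.68, 2.41 to 2.96), corneal endothelial-like (1.20, 0.73 to 1.68), stromal (0.97, 0.87 to 1.08) and vascular endothelial-like cells (0.57, 0.24 to 0.91) had higher shares. So did unnamed clusters led by Myh11 and Acta2 (4.54% against 0.184%) and by Ttr, Rgr and Rpe65 (1.40% against 0.498%). In the cluster led by Myh11 and Acta2 the melanocyte markers Pmel, Mlana, Tyrp1, Dct and Tyr were each found in 58% to 93% of cells. An unnamed cluster of low UMI content, led by Ptgds and Grem1 and with 3 melanocyte markers, held 9.48% against 0.0437%. Another low-content cluster held 0.00907% against 19.8%, and the 4 together 9.61% against 21.8%. Before doublets were removed, 149 mural-like cells with rapamycin and 24 with PBS lay in the cluster led by Chodl and Actg2. That led by Rgs5 and Higd1b held 60 and 11. Whether more of some eye tissues entered the rapamycin library was not tested. Neutrophil-like cells were 1.07% (0.887 to 1.28%) against 0.481% (0.362 to 0.625%) with a log2 ratio of 1.15 (0.68 to 1.64), and this turned to -0.31 when each cell was classed alone by its markers. Among immune cells alone the T cell log2 ratio was -2.42, and those of monocyte/macrophage-like and dendritic-like cells turned to 1.08 and 0.16. Genes of T cell-like cells were not compared, since the rapamycin library had 50 such cells.

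Monocyte/macrophage-like cells with rapamycin had lower interferon-gamma response genes, median -1.14 with 16 of 18 at least 1.5-fold lower, percentile 0, with Ly6a, an interferon-induced surface antigen, at 83.7 against 1019.8 CPM, log2 ratio -3.46. Glycolysis genes that mTORC1 drives were lower, median -1.27 with 11 of 12 at least 1.5-fold lower, with Gapdh, a glycolytic enzyme gene, at 563 against 1798 CPM, log2 ratio -1.66. Cxcl13, a chemokine that draws B cells, was 167 against 4.38 CPM, log2 ratio 3.62. Inflammatory myeloid genes had a median of 0.75 and genes of resident and alternatively activated macrophages 0.74. The C1q cluster held 68.1% of these cells with rapamycin and 21.2% with PBS. Within that cluster alone the interferon-gamma median was -1.49, with Cxcl9 at 16.7 against 947 CPM, log2 ratio -5.17. Dissociation stress genes were higher in the class, median 0.90, and the median ratio of genes with at least 50 UMIs in both libraries stood at -0.11 log2.

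Epithelial-like cells had lower interferon-gamma response genes (median -1.48 with 16 of 18 at least 1.5-fold lower) and lower class II genes (median -4.03), where genes with at least 50 UMIs in both libraries had a median of -0.18. Cd74 in them was 44.3 against 1177 CPM, log2 ratio -4.45, and with rapamycin stood at 0.264% of its CPM in immune cells, against a marker median of 0.0612% and at most 0.135% by cell type, so part of that remainder can be free RNA. The keratocyte cluster had lower interferon-gamma response genes (median -1.63), with Cxcl9 at 3.66 against 2039 CPM, 557-fold lower (270.1 to 1386), while Myc, a growth transcription factor, was 138 against 24.4 CPM, log2 ratio 2.11. Vascular endothelial-like cells had lower class II genes (median -3.45) and higher angiogenesis genes (median 0.98 with 8 of 10 at least 1.5-fold higher). Dll4, a Notch ligand of sprouting vessels, was 276 against 101 CPM, log2 ratio 1.36 there. The cluster led by Six3, Car8 and Esm1 held 46.7% of these cells with rapamycin and 17.3% with PBS, so these values span different clusters. Type I interferon genes were also higher in them (median 1.07 with 9 of 13 at least 1.5-fold higher), with Isg15, an interferon-induced ubiquitin-like protein, at 3057 against 948 CPM, log2 ratio 1.68.

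**Figure D2:**
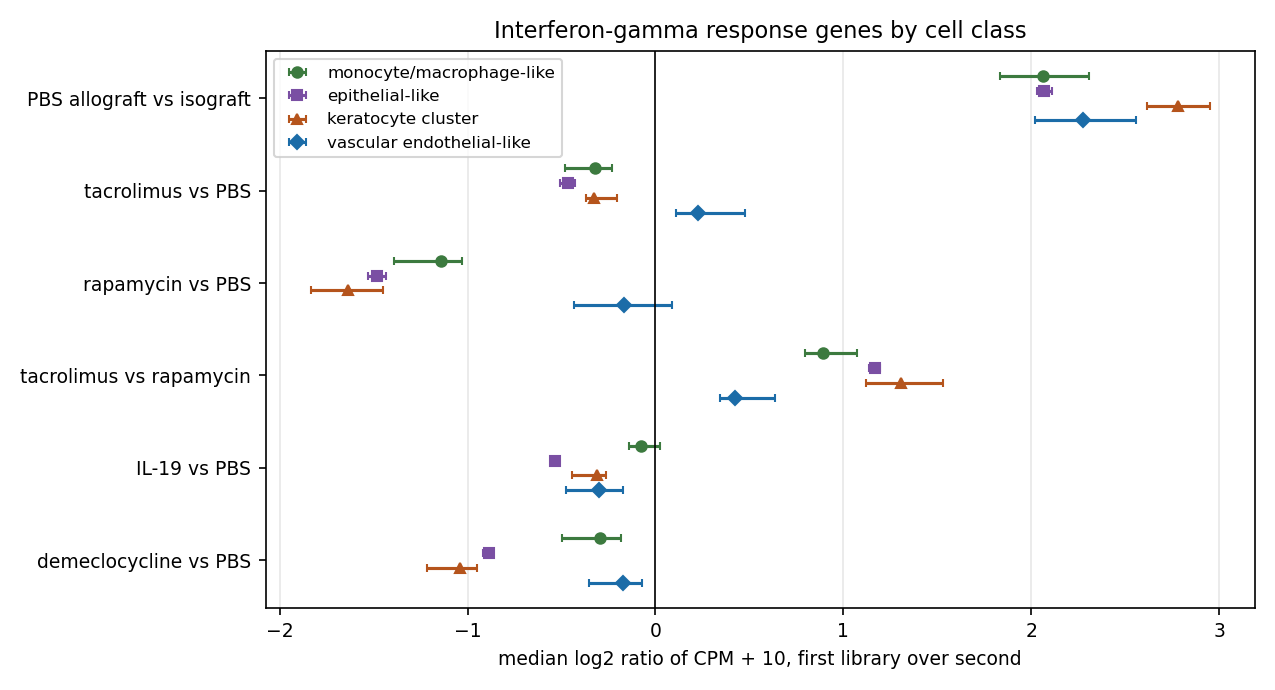
Median log2 ratio of the interferon-gamma response genes in 4 cell classes for 6 comparisons, on the scale of CPM + 10, with bars for the counting interval from redrawn counts. The PBS allograft lay above the isograft in each class (2.06 in monocyte/macrophage-like cells), and rapamycin against PBS stood at -1.14 in the same cells.

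Tacrolimus and rapamycin were set side by side with doses not given. T cell-like cells had a higher share with tacrolimus, log2 ratio 2.55 (2.12 to 3.01), and melanocyte-like (-3.06, -3.37 to -2.76), neutrophil-like (-2.10, -2.73 to -1.51), mural-like (-1.73, -2.16 to -1.32), corneal endothelial-like (-1.55, -2.08 to -1.06) and stromal cells (-0.96, -1.06 to -0.86) a lower one. Before doublets were removed, the mural-like cluster led by Chodl and Actg2 held 33 cells with tacrolimus and 149 with rapamycin. That led by Rgs5 and Higd1b held 35 and 60. Interferon-gamma response genes were higher with tacrolimus in monocyte/macrophage-like cells (median 0.89 with 13 of 18 at least 1.5-fold higher, where genes with at least 50 UMIs in both had a median of 0.15), in epithelial-like cells (median 1.17, where such genes had a median of 0.14) and in the keratocyte cluster (median 1.31). Serpina3g, a protease inhibitor that interferon-gamma raises, was 91.3 against 3.16 CPM, log2 ratio 2.94 in monocyte/macrophage-like cells. Vascular endothelial-like cells with tacrolimus had higher class II genes (median 2.65) and endothelial activation genes (median 1.51) and lower angiogenesis genes (median -0.69). The cluster led by Six3, Car8 and Esm1 held 14.2% of these cells with tacrolimus and 46.7% with rapamycin, and that led by Selp, Csf3 and Egr4 36.1% and 9.34%. Without epithelium the T cell log2 ratio was 3.12, and among immune cells alone 2.06.

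IL-19, a cytokine of the IL-10 family, was compared with PBS across 2 label sets, so that set and treatment cannot be told apart. T cell-like cells made up 10.4% (9.84 to 11.1%) with IL-19, a log2 ratio of -0.01 (-0.13 to 0.12), so a difference was not detectable at this depth among all kept cells. Neutrophil-like cells made up 1.48% (1.25 to 1.74%) against 0.481%, a log2 ratio of 1.62 (1.16 to 2.10). Mural-like (1.96, 1.36 to 2.60), vascular endothelial-like (0.61, 0.27 to 0.95), melanocyte-like (0.74, 0.41 to 1.07) and stromal cells (0.53, 0.42 to 0.65) had higher shares. Before doublets were removed, the mural-like cluster led by Rgs5 and Higd1b held 97 cells with IL-19 and 11 with PBS. That led by Chodl and Actg2 held 13 and 24. The T cell log2 ratio was -0.19 (-0.31 to -0.07) among immune cells alone, -0.16 (-0.28 to -0.03) without the clusters of low UMI content and -0.15 (-0.27 to -0.03) among named classes. Gamma-delta cells were 4.75% of T cell-like cells and regulatory cells 20.2%, against 11.4% and 12.9% with PBS.

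T cell-like cells with IL-19 had lower type 17 genes, median -0.66, beside the lower gamma-delta share. CD8 cells had higher proliferation genes, median 0.60 with 11 of 21 at least 1.5-fold higher. In monocyte/macrophage-like cells Arg1, the arginase of wound macrophages (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), was 1546 against 268 CPM, log2 ratio 2.49, Nos2, the inducible nitric oxide synthase, 145 against 35.6 CPM, log2 ratio 1.76, and Cxcl13, a chemokine that draws B cells, 46.3 against 4.38 CPM, log2 ratio 1.97. Their interferon-gamma response genes had a median of -0.08, at percentile 15.2 and so within the random range. Dendritic-like cells had higher chemokine genes (median 1.48), and Areg, an epidermal growth factor receptor ligand, at 135 against 7.54 CPM, log2 ratio 3.05. In the keratocyte cluster Saa3, an acute-phase serum amyloid, was 5636 against 941 CPM, log2 ratio 2.57, Mmp3, the stromelysin of matrix breakdown, 5473 against 2313 CPM, log2 ratio 1.24, and Tgtp2, an interferon-induced GTPase, 14.9 against 195 CPM, log2 ratio -3.04. Epithelial-like cells had lower type I interferon genes (median -0.88), and Lcn2, an iron-binding acute-phase protein, was 31.8 against 485 CPM, log2 ratio -3.56 in vascular endothelial-like cells, of which the cluster led by Selp, Csf3 and Egr4 held 35.3% with IL-19 and 11.8% with PBS. In T cell-like cells haemoglobin genes had a median of -4.39 and dissociation stress genes -0.71.

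Demeclocycline against PBS also spanned the 2 label sets. T cell-like cells made up 2.12% (1.88 to 2.38%), a log2 ratio of -2.31 (-2.50 to -2.12), and NK-like (-2.49, -3.01 to -2.00), dendritic-like (-1.65, -2.13 to -1.19) and monocyte/macrophage-like cells (-1.01, -1.20 to -0.81) had lower shares. Among immune cells alone the T cell log2 ratio was -0.63, and those of monocyte/macrophage-like and dendritic-like cells turned to 0.67 and 0.0261. Calcineurin and NFAT genes in CD4 cells had a median of 1.09 with 10 of 15 at least 1.5-fold higher, with Csf2, the gene of the growth factor GM-CSF, at 137 against 19.2 CPM, log2 ratio 2.33, and naive and memory genes a median of -1.51. Gzmf, a granzyme, was 0 against 143 CPM, at least 50.5-fold lower in all T cell-like cells. In these dissociation stress genes were higher (median 0.73) and haemoglobin genes lower (median -4.82).

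The keratocyte cluster with demeclocycline had lower interferon-gamma response genes, median -1.04 with 16 of 17 at least 1.5-fold lower, and lower dissociation stress genes, median -1.14. Cxcl9 in it was 426 against 2039 CPM, log2 ratio -2.23 and Tgtp2, an interferon-induced GTPase, 8.78 against 195 CPM, log2 ratio -3.45. Epithelial-like cells had lower interferon-gamma response genes (median -0.89) and class II genes (median -1.62). Monocyte/macrophage-like cells had lower type I interferon genes, median -0.94, and -0.71 within the C1q and -0.63 within the Ly6c2 cluster. These held 45.9% and 33.2% of the class with demeclocycline, and 21.2% and 67.1% with PBS. Over the whole class Il12b, a subunit of a cytokine that drives interferon-gamma, was 4.36 against 63.9 CPM, log2 ratio -2.36 and Ccr7, the lymph node homing receptor, 18.7 against 136 CPM, log2 ratio -2.35.

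**Figure D3:**
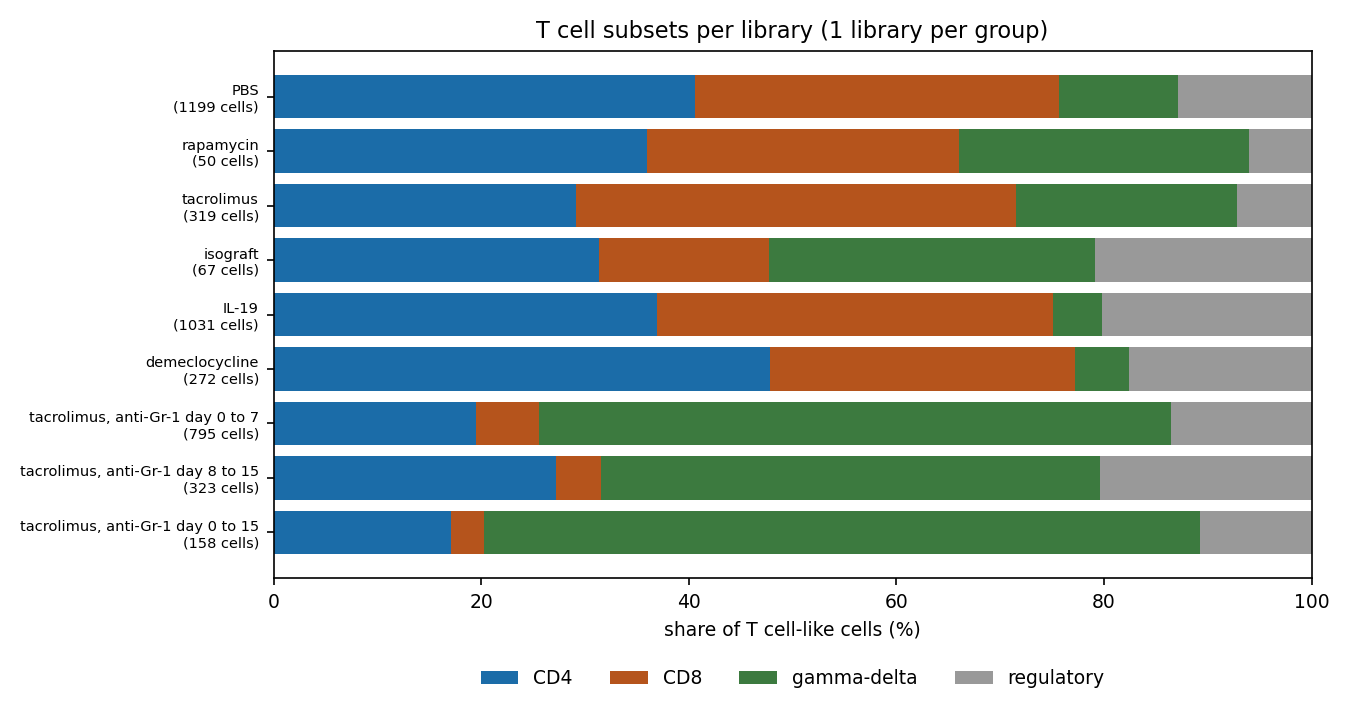
Share of T cell-like cells (percent) in 4 subsets for each library, with the number of cells beside its name. CD8 cells made up 35% with PBS and 42.3% with tacrolimus, and gamma-delta cells 60.9% in the library labelled day 0 to 7.

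The antibody libraries were compared with tacrolimus alone, of the other label set, to ask how grafts differ when the antibody is given over different days. Set and antibody cannot be told apart. Nor can a separate counting or processing of the antibody libraries, which stood apart from IL-19 and demeclocycline of their own set too. Neutrophil-like cells made up 10.4% (9.89 to 11%) in the library labelled day 0 to 7, 3.37% (2.95 to 3.84%) in that labelled day 8 to 15 and 0.642% (0.496 to 0.817%) in that labelled day 0 to 15, against 0.250% (0.169 to 0.356%) with tacrolimus alone. The log2 ratios were 5.38 (4.86 to 5.96), 3.76 (3.20 to 4.36) and 1.36 (0.72 to 2.04), and 3.34, 2.28 and 2.27 among immune cells alone. With at least 500 genes per cell those of the first and second were 4.56 and 4.38, and without epithelium that of the last was 2.58. Monocyte/macrophage-like cells had higher shares in the first (1.23, 1.05 to 1.41) and second (1.27, 1.07 to 1.47) and a lower one in the last (-1.75, -2.10 to -1.41), and T cell-like cells likewise with log2 ratios of 1.27 (1.08 to 1.46), 0.88 (0.65 to 1.11) and -0.77 (-1.05 to -0.49). Among immune cells alone the T cell log2 ratios turned to -0.77, -0.59 and 0.15, and those of monocyte/macrophage-like cells in the first and second turned to -0.81 and -0.20. Without epithelium the T cell log2 ratio of the last turned to 0.45. Gamma-delta cells made up 60.9%, 48% and 69% of T cell-like cells, but they and the macrophages lay in other clusters than those of tacrolimus alone, with 97%, 97.3% and 93.3% of the monocyte/macrophage-like cells in the Mmp12 cluster. The Ly6c2 cluster, of monocytes that Gr-1 also marks, held 1.38%, 0.632% and 0% of them against 24.6% with tacrolimus alone, though the Mmp12 cluster lay mostly in these libraries and may be theirs and not a type. Neutrophil-like cells also lay mostly in other clusters than those of tacrolimus alone. Before doublets were removed, the cluster led by Cstdc4 and Acod1 held 1228, 171 and 35 of them, against 7 with tacrolimus alone. The cluster led by Camp held 74, 45 and 30 against 0, and that led by G0s2 and Lrg1 0, 9 and 0 against 23.

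Chchd2 and Gnb2, housekeeping genes of mitochondrion and G protein, were among the leading genes higher in T cell-like cells of these libraries, and were at 0 in those of tacrolimus alone. In T cell-like cells of the library labelled day 0 to 7, Chchd2 was 397 against 0 CPM, at least 116-fold higher. The median mitochondrial share per barcode was 1.76%, 1.86% and 1.76%, against 0.263% with tacrolimus alone. With IL-19 and demeclocycline, of the same label set as the antibody libraries, it was 0.245% and 0.266%. RNA quality genes in T cell-like cells of the antibody libraries had medians of 1.83, 1.65 and 1.79. Genes of epithelial-like cells with at least 50 UMIs in both libraries had median log2 ratios of 0.37, 0.39 and 0.29. Genes were therefore compared between the antibody libraries, which was decided after the data had been seen.

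The library labelled day 0 to 15 had lower shares than that labelled day 0 to 7 of neutrophil-like (-4.02, -4.40 to -3.66), NK-like (-3.98, -5.22 to -2.97) and monocyte/macrophage-like cells (-2.98, -3.31 to -2.66). All immune classes together made up 3.48% against 26.9%. Monocyte/macrophage-like cells were 90 of 352 immune cells against 870 of 3343, a similar part. Neutrophil-like cells were 65 against 1295 of these immune cells, and NK-like cells 8 against 155. Interferon-gamma response genes of the library labelled day 0 to 15 were lower in T cell-like cells (median -1.18 with 17 of 18 at least 1.5-fold lower), in stromal cells (median -1.37), in vascular endothelial-like cells (median -1.42) and in epithelial-like cells (median -1.46). T effector genes had a median of -1.41 in T cell-like cells, and of -0.76 with 3 of 6 at least 1.5-fold lower in gamma-delta cells alone. These were 69% of T cell-like cells against 60.9%, and CD8 cells 3.16% against 6.04%. Il10, a suppressive cytokine gene, was 3.17 against 52.9 CPM, 16.7-fold lower with an interval of 2.92 to 668 in T cell-like cells. Cxcl9 was 23.7 against 575 CPM, log2 ratio -4.11 in stromal cells. Calca, the gene of the neuropeptide CGRP, was 295 against 33.7 CPM, log2 ratio 2.80 in T cell-like cells.

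The library labelled day 8 to 15 was close to that labelled day 0 to 7 in monocyte/macrophage-like share (0.04, -0.13 to 0.20), a difference within counting error. Neutrophil-like cells had a lower share (-1.63, -1.84 to -1.42) and stromal cells a higher one (2.07, 1.85 to 2.29). Neutrophil-like cells held Wfdc17, a secreted protein of activated myeloid cells, at 5924 against 1285 CPM, log2 ratio 2.20, and higher interferon-gamma response genes (median 0.63 with 10 of 17 at least 1.5-fold higher). The cluster led by Camp held 19.3% of them in this library and 5.71% in that labelled day 0 to 7, and the cluster led by Cstdc4 and Acod1 76.7% and 94.3%.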

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

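The tests in this part were chosen after the result was seen, except that of genes sharing exon bases with a neighbour.

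Genes of the 3 antibody libraries stood apart from those of the other 6 libraries, with 42 genes counted in each of the 3 and at no more than 3 UMIs in the others, and 0 the other way. Across genes, intron length and the log2 ratio had a Spearman's rho of at least 0.374 and up to 0.541 in 3 classes, beyond the 0.224 of 1 of the other 6 against the rest, which is consistent with reads in introns counted only in the 3. Genes that share exon bases with another gene on the same strand made up 47.6% of those genes (20 of 42) against 2.14% of matched genes, less than the level set for dropped overlapping reads as the cause, so that part stays open. The 3 libraries were those given the antibody. The 42 genes included housekeeping genes such as Chchd2 and Gnb2, at means of 448 and 491 CPM in the 3. In no library without antibody, the untreated isograft included, did they exceed 0 and 2 UMIs. That near absence argues against the antibody as the cause for these 42 genes. For other genes the antibody stays open and was not tested.

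Genes that calcineurin and NFAT drive were higher, by less than 1.5-fold, in T cell-like cells with tacrolimus, a calcineurin blocker, than with PBS, median 0.37. CD8 cells alone gave 0.31 (0.08 to 0.69), which argues against the mix of subsets as the whole cause. Cells thinned to 1000 UMIs gave 0.76 (0.54 to 0.99), which argues against depth per cell. Without Egr1, Egr2, Egr3, Nr4a1, Nr4a2 and Nr4a3 the median was 0.0776 (-0.17 to 0.31), so genes switched on while cells were dissociated may carry it and cannot be told apart from the drug.

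Neutrophil-like cells had higher shares in the libraries labelled with the neutrophil-binding antibody than with tacrolimus alone, which lay in the other label set. Set, antibody and a separate counting or processing of the antibody libraries cannot be told apart. The neutrophil-like cells also lay mostly in other clusters than those of tacrolimus alone. Among cells of at least 2000 UMIs they were 95 of 9910, 48 of 6114 and 10 of 9492 in the libraries labelled day 0 to 7, day 8 to 15 and day 0 to 15, and 1 of 9318 with tacrolimus. The ratio was at least 73.2 (lower limit 12.5) for the first and second and 9.82 (lower limit 1.40) for the last, and rests on that single tacrolimus cell. Reads in introns may have been counted only in the antibody libraries, so 2000 UMIs need not mark the same depth in both. Shallow cells as the cause therefore stay open. Neutrophils that came back after the antibody ended may explain the library labelled day 0 to 7, while over all cells the lower ratio of the 2 labelled to day 15 was 2.57 (lower limit 1.64), and the cells of at least 2000 UMIs left this open. A wrong label, which the conflict of titles raises, was not tested.

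Lists that stood at least 1.5-fold apart in opposite directions in 2 classes of the same comparison are given here if both medians lay outside the central 95% of random lists, and none of these differences was tested. Type I interferon genes with rapamycin against PBS had medians of 1.07 in vascular endothelial-like and -0.84 in epithelial-like cells, 1.91 apart. MHC class II genes with IL-19 against PBS had medians of 0.95 in T cell-like and -1.30 in vascular endothelial-like cells, 2.25 apart. Free RNA of other immune cells was not gauged in T cell-like cells, so the class II counts there need not be their own. Dissociation stress genes with demeclocycline against PBS had medians of 0.73 in T cell-like and -1.21 in stromal cells, 1.94 apart.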

How the results depend on the processing

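The denominators without clusters of low UMI content and with named classes only, the C1q cluster alone, and the comparisons between antibody libraries were chosen after the data had been seen. The cause of each difference was not tested, unless stated. Over 81 settings of the 9 main shares, 61 stayed within the counting interval, 20 moved beyond it and 0 changed direction, and over 30 settings of the 3 main list medians the counts were 26, 4 and 0. Of 754 settings of 91 other shares 570 stayed, 161 moved and 23 turned, of 1477 settings of 428 other list medians 963 stayed, 501 moved and 13 turned, and of 756 settings of 276 named genes 638 stayed and 118 moved. No paired analysis was possible because each group had 1 library.

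Among immune cells only, a denominator that itself differs between libraries, the T cell log2 ratio was 0.55 for PBS against the isograft, -0.36 for tacrolimus, -2.42 for rapamycin, -0.19 for IL-19 and -0.63 for demeclocycline against PBS, and 2.06 for tacrolimus against rapamycin. For the libraries labelled day 0 to 7, day 8 to 15 and day 0 to 15 against tacrolimus it turned to -0.77, -0.59 and 0.15, and the neutrophil ratio was 3.34, 2.28 and 2.27. The monocyte/macrophage ratio turned to -0.82 for PBS against the isograft, 0.79 for tacrolimus, 1.08 for rapamycin, 0.67 for demeclocycline, and -0.81 and -0.20 for day 0 to 7 and day 8 to 15. The dendritic ratio turned to -0.40 for PBS against the isograft, 0.16 for rapamycin, 0.0261 for demeclocycline and -0.48 for day 0 to 7. Between day 0 to 15 and day 0 to 7 the T cell ratio turned to 0.92 and the dendritic ratio to 0.25.

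Without epithelium the T cell ratio was 2.41 for PBS against the isograft, -1.40 for tacrolimus against PBS and 3.12 for tacrolimus against rapamycin. For day 0 to 15 against tacrolimus the T cell ratio turned to 0.45, the stromal ratio turned to 0.16 and the neutrophil ratio was 2.58, and against day 0 to 7 the vascular ratio turned to 0.59. Without clusters of low UMI content the T cell ratio was -0.16 for IL-19 and -2.10 for demeclocycline, and with named classes only -0.15 and -2.11. With each cell classed alone by its markers, the T cell ratio was -1.96 for demeclocycline, the neutrophil ratio turned to -0.31 for rapamycin, the melanocyte ratio to 0.67 for demeclocycline, and the dendritic and Schwann ratios to -0.28 and -0.23 for day 0 to 7. Resolution 2 turned the melanocyte ratio for day 0 to 15 against tacrolimus to 0.56. With at least 500 genes per cell the neutrophil ratio was 4.56 for day 0 to 7 and 4.38 for day 8 to 15.

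Interferon-gamma response genes of monocyte/macrophage-like cells had a median of 2.51 for PBS against the isograft with a pseudocount of 1 CPM, which widens ratios of low genes by construction. Thinned cells gave -0.76 for tacrolimus and -1.49 for rapamycin, and the C1q cluster alone -1.49 for rapamycin. With doublets kept, the median turned to 0.32 for fibrosis genes in melanocyte-like cells with tacrolimus, -0.0700 for regulatory T cell genes in monocyte/macrophage-like cells with demeclocycline, 1.47 for inflammatory genes in T cell-like cells of day 8 to 15 against tacrolimus, and 0.0160 for these and 0.23 for class II genes against day 0 to 7. With thinned cells it turned to 1.10 for chemokines in melanocyte-like cells with tacrolimus, 0.26 for type I interferon genes in vascular cells with IL-19, -0.36 for the same regulatory list with demeclocycline, and 0.62 for inflammatory genes in stromal cells of day 0 to 15 against day 0 to 7. Proliferation genes turned to 0.14 in monocyte/macrophage-like cells of day 0 to 7 against tacrolimus, to 0.34 in neutrophil-like and -0.16 in vascular cells of day 8 to 15 against day 0 to 7, and to -0.20 in vascular cells of day 0 to 15 against day 0 to 7.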

Other observations

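No test was made in this part. Corneal endothelial-like cells, which keep the cornea clear by pumping fluid, made up 0.490% (0.370 to 0.635%) of kept cells with PBS, 1.12% (0.936 to 1.34%) with rapamycin, 0.383% (0.281 to 0.510%) with tacrolimus, 0.332% (0.225 to 0.470%) in the isograft, 0.385% (0.272 to 0.528%) with IL-19 and 0.0935% (0.0483 to 0.163%) with demeclocycline. In the library labelled day 0 to 7 they were 0 of 12420 cells, with an upper limit of 0.0297%. In the library labelled day 0 to 15 they were 0 of 10129 cells, with an upper limit of 0.0364%. In the library labelled day 8 to 15 they were 1 of 6612 cells. In the same order, the keratocyte cluster held only 1 of 253, 8 of 489 and 3 of 565 stromal cells. With tacrolimus alone it held 414 of 1205. In that order 37.2%, 49.9% and 50.4% of stromal cells lay in the cluster led by Matn4 and Thbs2, against 2.90% with tacrolimus alone. Before doublets were removed, the keratocyte genes Kera and Lum were found in 40% and 95% of that cluster's cells. Keratocytes of the antibody libraries may therefore lie there, and these counts do not show their loss. Whether the tissue taken or its processing differed in these libraries was not tested.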
